A study of Homo sapiens with 32 samples.

How the data were processed

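Gene expression was measured in 2 human colon cancer cell lines, RKO and Caco-2, on 32 Agilent 2-colour arrays, 16 per line. Per the labels, cells were plated overnight, pretreated for 1 hr with 100 ng/ml tumour necrosis factor alpha (TNF) or bovine serum albumin (BSA, the control protein), and exposed for 4 hr to particles or to medium. The particles were nano-sized ZnO, Fe2O3, SiO2, TiO2, Al2O3 and carbon black (nanoCB) and micron-sized ZnO (microZnO). The doses were 5 µg/cm2 for both forms of ZnO, 10 for nanoFe2O3 and 50 for the others. Every array carried the treated sample in Cy5 and BSA-pretreated control RNA of the same line in Cy3, and the dyes were never exchanged. Each array held RNA pooled from 4 independent samples, or 3 for cells given TNF without particles, so an array is a pool and not 1 culture. Each line had 2 arrays of TNF alone, and each particle had 1 array with TNF and 1 with BSA.

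The authors scanned the arrays at 5 micron and extracted the spots with Agilent Feature Extraction 9.5.1.1. Per the file headers, the mean spot signals and local backgrounds are raw intensity values in both channels, and the processed signals are intensity values after background subtraction and LOWESS dye normalization. Per the file headers, LogRatio is the log10 of the processed Cy5 signal over the processed Cy3 signal. The columns for saturated, non-uniform or well-above-background spots are flags per the file headers, with no other unit. The deposited series table gives log2 ratios of Cy5 over Cy3, rounded to 2 decimals, and its median is 0 in every column. It was checked against LogRatio converted to log2: for 29 of 32 arrays, 100% of 45015 spots agreed within 0.006. The other 3 columns, Caco-2 with BSA and nanoSiO2, TNF and nanoTiO2, and BSA and nanoTiO2, agreed for 16.66%, 16.91% and 16.17% of spots. The cause is unknown, and the table served only as an alternative.

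The mean signals were background-corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array (R 4.3.3, limma 3.58.1, data.table version 1.17.8). Of 45015 spots, 1639 were controls and the rest stood for 41000 probes. Probe coordinates are those of the array design, on hg17 (NCBI35). Gene names were updated with a RefSeq table of GRCh38.p14, used for names only: 23434 probes matched by accession, 2317 by symbol and 1043 by older symbol, and 14206 stayed unnamed. Of the 17519 named genes, 6887 had several probes, and the probe with the highest mean signal was taken. A gene was tested in a line if its probe was well above background on at least 2 of the 16 arrays, and 16304 genes were fitted.

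One limma model took all 32 arrays, with a reference term, a TNF term and 7 particle terms per line (14 residual degrees of freedom, plus 4.02 from the moderated variance, whose prior SD was 0.073). TNF effects therefore rest on 7 pairs of TNF and BSA arrays per line that share particle and slide. Particle effects are changes against the 2 arrays of TNF alone, on the assumption that TNF and particle effects add on the log2 scale. Each particle has 1 array per pretreatment, so a left-out array leaves 1, which is then assumed to vary like the others. Both arrays of a particle share a slide, so the p-values for particles leave out the spread between slides and cultures. The comparisons were TNF in each line, each particle in each line, nanoZnO against microZnO in each line, the difference between lines for TNF, nanoZnO and microZnO, and a term for TNF by particle, added for 1 particle at a time. P-values from limma are two-sided and Benjamini-Hochberg adjusted within a comparison, or over the 7 particles of a line for TNF by particle. A gene passed with an adjusted p under 0.05. Values are log2 changes with ± 1 SE.

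A total of 17 gene lists per comparison were tested with camera (limma, preset correlation 0.01): metallothioneins and zinc export, other zinc transporters, heat shock response, oxidative stress (NRF2 targets), integrated stress response (ATF4 targets), endoplasmic reticulum chaperones, immediate early genes, NF-kB targets, interferon response, p53 targets, cell cycle, hypoxia response, iron handling, aryl hydrocarbon receptor targets, cholesterol synthesis, lysosome and autophagy, and non-epithelial cell markers. Another list, enterocyte markers, served to check cell-line labels. The groups, comparisons, lists and the rule for naming genes were fixed before the data were examined. Named genes passed the test, had a symbol, and moved the same way in all 7 pairs (TNF) or in both arms (particles, nano against micro); differences between lines and TNF by particle had no such requirement. They are the 8 largest rises and falls for TNF, nanoZnO and microZnO, the 4 largest for nano against micro and for line differences, the 3 largest for each other particle and for TNF by particle, plus up to 4 members of a list with the largest change. Not every gene picked is printed.

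The steps were tested on simulated data with 50 changed genes per fold size among 13357. For TNF in RKO, 92% of genes changed 1.25-fold and 100% of those changed 1.5-fold were recovered, and 6.7% of the calls were false. For nanoZnO in RKO the shares were 58% and 92%, with 4.9% false. For the TNF difference between lines they were 82% and 96%, with 4.1% false. For TNF by nanoZnO in Caco-2, with 2-fold changes, 189 of 200 genes were recovered. The simulation had no spread between slides.

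The arrays sat on 8 slides of up to 4 arrays, and the slide with all microZnO arrays was scanned 332 days after the first. Adding slide to the model leaves its rank at 18, so slide is already contained in its terms. Alternatives were the ratio against 0 without the reference term, no background subtraction, Agilent's processed log ratios, the deposited table, no filter or a stricter filter (8 arrays) on dim probes, a separate fit for each line, TNF alone against 0, and leaving out each array in turn. Another 5 were added after seeing the data. These were each particle against the particles without zinc of its line, and all transcripts including unnamed ones. The rest were leaving out the Caco-2 nanoZnO arrays, leaving out the microZnO arrays, and nanoZnO against nanoFe2O3 on their shared Caco-2 slide. No sample was left out of the main results.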

Results

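The data are 32 two-colour array profiles of 2 colon cancer cell lines, RKO and Caco-2, exposed to particles with or without TNF, a cytokine that drives inflammation. Each line had 16 arrays: 2 of TNF alone and, for each of 7 particles, 1 with BSA and 1 with TNF. The median spot intensity ranged from 159 to 362.3 in Cy3 and from 255.1 to 631.7 in Cy5 across arrays. Between 58% and 86.6% of Cy5 spots were well above background, and between 59.1% and 83.4% of Cy3 spots. The number of arrays limits the precision of every value. Enterocyte markers, genes of the absorptive gut cell, had a mean log2 Cy3 signal of 6.75 to 6.98 in RKO and 10.55 to 10.66 in Caco-2. By Cy3, the control RNA, 0 of 32 arrays resembled the other line more than their own. In Cy5, the treated sample, the marker mean was 6.76 to 6.93 in RKO and 9.75 to 11.3 in Caco-2. On the RKO microZnO arrays it was 6.93 with TNF and 6.87 with BSA. The descriptions of the 2 RKO microZnO arrays name Caco-2, while their titles and cell-line labels and their signal are those of RKO, and they were taken as RKO.

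TNF raised NF-kB targets in RKO cells. The largest rise was BIRC3, an inhibitor of cell death, at 4.68 ± 0.10 on the log2 scale (7 pairs, 25.7-fold; chromosome 11, 101713566 to 101713625, hg17; adjusted p = 3.5e-16). NFKBIA, which restrains NF-kB, rose by 3.59 ± 0.22 (12.1-fold; chromosome 14, 34940539 to 34940598; adjusted p = 1e-09), and ICAM1, an adhesion molecule for leukocytes, by 3.51 ± 0.11 (chromosome 19, 10257298 to 10257358). The chemokines CXCL1, CXCL3 and CXCL8 rose by 3.12, 2.53 and 2.46, TRAF1, an adaptor of TNF receptors, by 2.76, and TNFAIP3, a brake on NF-kB, by 2.40. A second probe gave 1.1 for CXCL3 and 0.94 for TNFAIP3. CXCL8 was well above background on 3 of the 7 BSA arrays, and its rise ranged from 2.16 to 4.26 over its alternatives. Falls were smaller: the transcription factor RUNX2 fell by 0.70 ± 0.061 (adjusted p = 1e-07), EMP1 by 0.66, the Notch ligand JAG1 by 0.62, the cytokine IL11 by 0.59, CCN3 by 0.51, the peptide hormone APLN by 0.51, KIF26B by 0.49 and ANGPTL4, an inhibitor of lipoprotein lipase, by 0.48. Other probes gave values near 0 for RUNX2 (0.04) and APLN (0.06).

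The comparison asked which genes respond to TNF whatever the particle, and the limma test called 2529 of 13608 genes in RKO, 1268 higher and 1261 lower. Of these, 49 rose and 0 fell at least 2-fold, while 4045 genes had an unadjusted p under 0.05. Of 38 measured NF-kB targets, 33 rose, 0 fell and 5 did not pass, with a median of 1.07 (34 higher when adjusted over the list alone; camera adjusted p = 6.9e-54, and adjusted p = 0.00012 with an estimated correlation). Of 29 interferon response genes, 12 rose, among them GBP2 (1.57), and IFIH1 (1.44) and RIGI (0.83), sensors of viral RNA; 13 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.2e-08, adjusted p = 0.086 with an estimated correlation). Of 11 genes for metallothioneins and zinc export, which bind zinc or carry it out of the cell, 9 rose with a median of 0.22, such as MT1A (0.30) and MT1E (0.27), and 9 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00017, adjusted p = 0.53 with an estimated correlation). Of 28 p53 targets, 8 rose, led by the death receptor TNFRSF10B (0.86), and 8 did so adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation). With the ratio against 0 its adjusted p was 0.087, within a range of 0.00092 to 0.32 over all alternatives.

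Smaller shifts in RKO were heat shock genes, immediate early genes and NRF2 targets. Of 24 heat shock genes 3 rose, the same number adjusted over the list alone (camera adjusted p = 0.0053, adjusted p = 0.58 with an estimated correlation). Of 28 immediate early genes, transcribed within minutes of a stimulus, 7 rose, such as JUNB (1.01), and 1 fell, KLF2 (-0.47); 9 and 1 were called adjusted over the list alone (camera adjusted p = 0.006, adjusted p = 0.75 with an estimated correlation). Of 23 NRF2 targets 4 rose, among them SQSTM1 (0.60) and TXNRD1 (0.58), as many adjusted over the list alone (camera adjusted p = 0.006, adjusted p = 0.58 with an estimated correlation). The other 10 lists did not pass: for example, 0 of 8 non-epithelial cell markers were called (camera adjusted p = 0.78). The EMP1 fall ended when TNF alone was set against 0 (-0.06, adjusted p = 0.27; range 6.1e-08 to 0.27 over its alternatives).

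In Caco-2 cells TNF raised NF-kB targets and interferon response genes. CCL2, which draws in monocytes, rose by 2.85 ± 0.073 (7 pairs, 7.19-fold; chromosome 17, 29608163 to 29608222; adjusted p = 1.1e-14), the cytokine LTB by 2.78 ± 0.11, and BIRC3 by 2.36. The ubiquitin-like UBD rose by 2.35, COXFA4L3 (C15orf48 on the array) by 2.23, the protease inhibitor TFPI2 by 2.06, the death receptor FAS by 2.02 and the peptide transporter TAP1 by 2.01. Among falls were FAM78A (-0.94), MTUS2 (-0.83), SPTSSB (-0.79), the kinase MAP2K6 (-0.71), ID2 (-0.69), G0S2, an inhibitor of fat breakdown (-0.67), HEYL (-0.65) and the oestrogen receptor GPER1 (-0.65). The test called 4821 of 16179 genes, 1905 higher and 2916 lower, with 44 rises and 0 falls of at least 2-fold and 6397 genes at an unadjusted p under 0.05.

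Of 41 NF-kB targets in Caco-2, 34 rose and 1 fell, with a median of 0.72 (35 and 1 adjusted over the list alone; camera adjusted p = 6e-35, and adjusted p = 0.0018 with an estimated correlation). CXCL10 was among them (1.84). Of 30 interferon response genes 18 rose, such as TAP1, IFIH1 (1.46), RIGI (1.08) and the immunoproteasome subunit PSMB9 (0.75), and 18 did so adjusted over the list alone (camera adjusted p = 2.7e-12, adjusted p = 0.029 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 7 fell, led by HERPUD1 (-0.51), and 9 fell adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.83 with an estimated correlation). That call also ended with the ratio against 0, no background subtraction, the deposited table or the stricter filter (0.16, 0.053, 0.056 and 0.054; range 0.018 to 0.83). The other 14 lists did not pass. For non-epithelial cell markers, 3 of 14 rose, with CDH5 at 0.63, and 2 fell (camera adjusted p = 0.91).

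**Figure D1:**
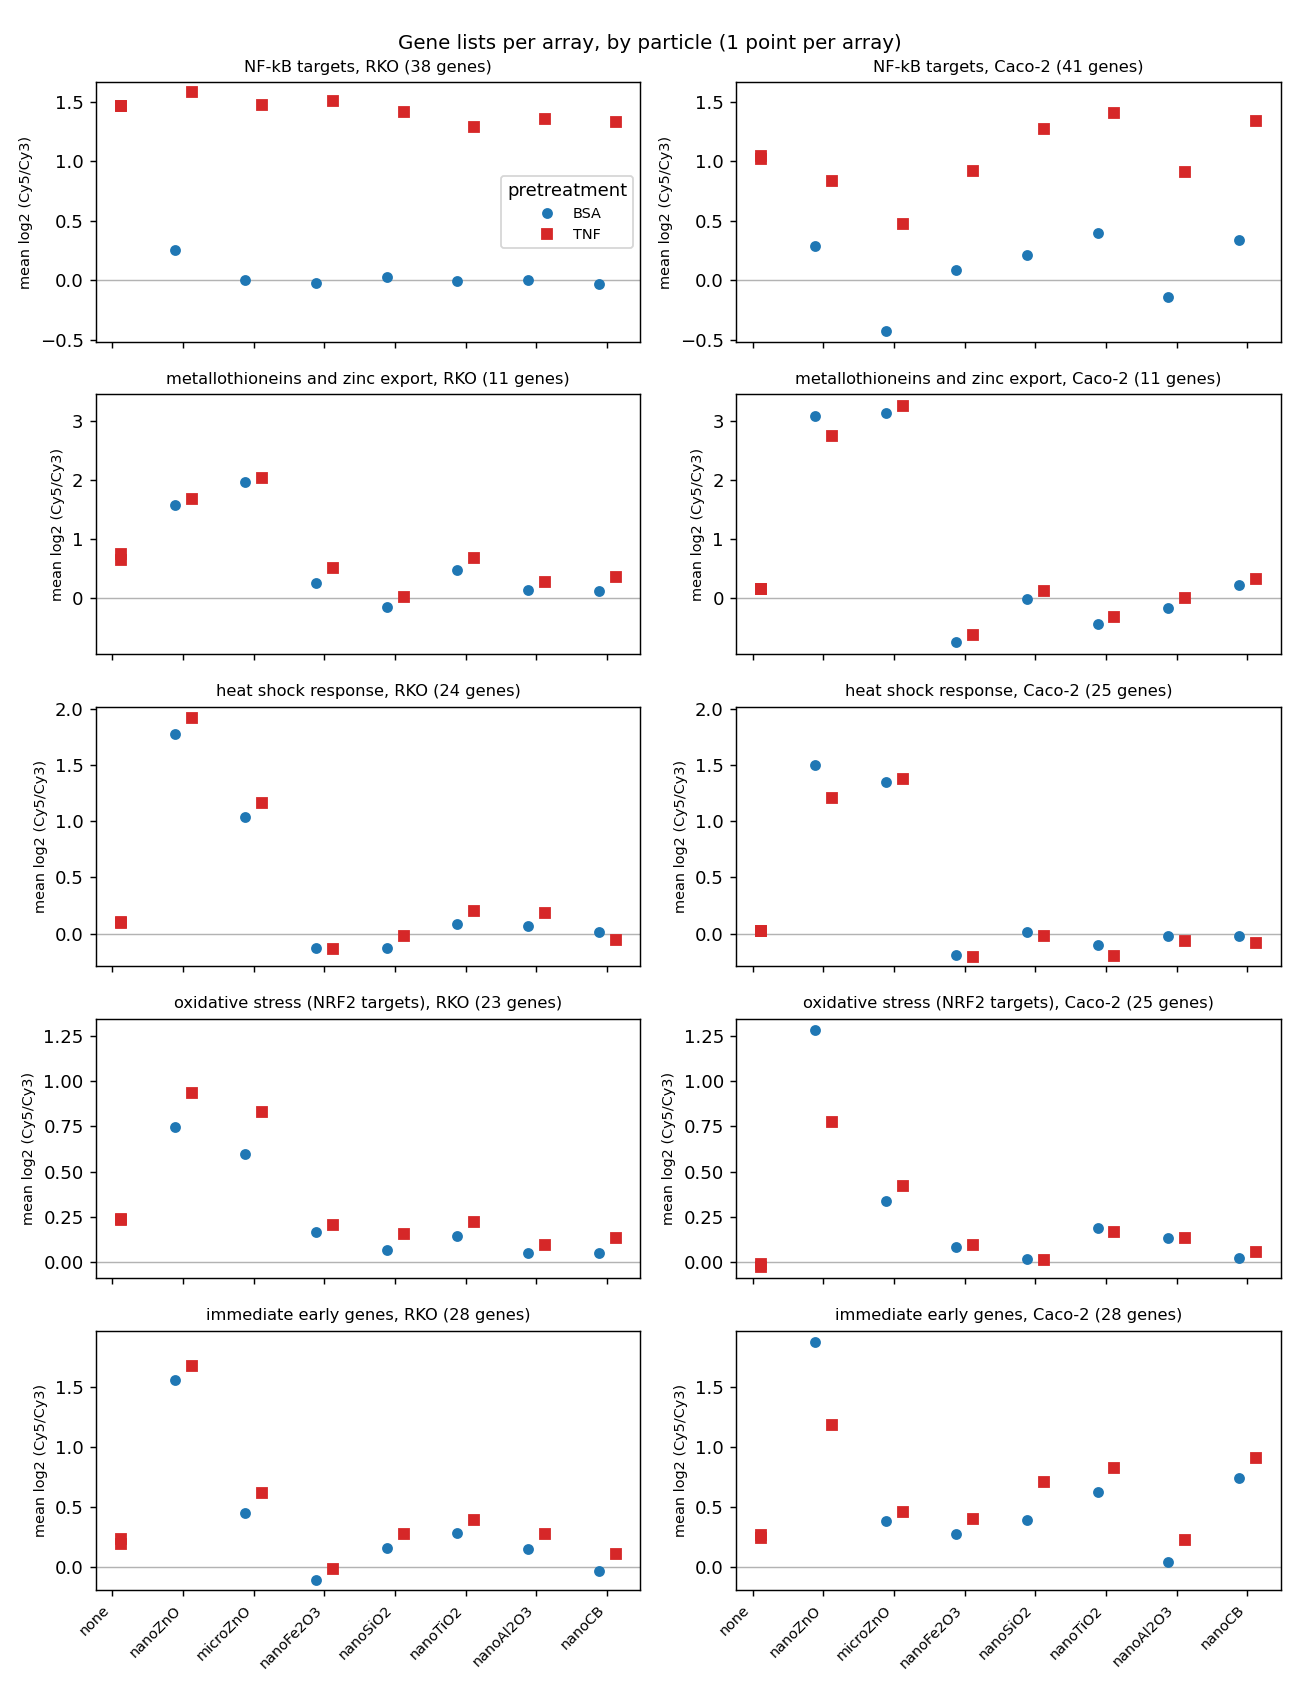
Each point is 1 array: the mean log2 ratio of Cy5 (treated) over Cy3 (BSA control) of a gene list, for BSA (circles) and TNF (squares) arrays, by particle, with RKO on the left and Caco-2 on the right. NF-kB targets are higher in every TNF square than in the BSA circle of the same particle, and metallothioneins and heat shock genes are highest with nanoZnO and microZnO.

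The lines differed in how strongly TNF moved single genes. TRAF1 rose by 2.76 ± 0.10 in RKO and was 0.16 ± 0.10 in Caco-2, a difference of 2.60 ± 0.14 (adjusted p = 1.3e-09), and the differences of BIRC3, ICAM1 and NFKBIA were 2.32, 2.27 and 2.06. In the other direction, COXFA4L3 was 0.01 in RKO against 2.23 in Caco-2 (difference -2.22 ± 0.13), the plasminogen activator PLAT -0.09 against 1.84 (-1.93), UBD 0.43 against 2.35 (-1.92) and CXCL10 0.02 against 1.84 (-1.82). FAS (-1.50) and TAP1 (-1.32) also rose more in Caco-2, and GBP2 (1.34) more in RKO. The test of the difference called 2152 of 13500 genes, 1316 higher and 836 lower in RKO.

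Of 38 NF-kB targets, 20 were more positive in RKO and 5 in Caco-2 (22 and 5 adjusted over the list alone; camera adjusted p = 1.7e-09, adjusted p = 0.22 with an estimated correlation). Heat shock genes differed for 7 of 24, all toward RKO, such as DNAJB4 (0.59), and for 8 adjusted over the list alone (camera adjusted p = 0.00033, adjusted p = 0.71 with an estimated correlation). Endoplasmic reticulum chaperones differed for 6 of 18, such as HERPUD1 (0.64), and for 8 adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.71 with an estimated correlation). NRF2 targets differed for 6 of 23, such as TXNRD1 (0.46), and for 7 adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.71 with an estimated correlation). With the stricter filter the adjusted p for NRF2 targets was 0.055, in a range of 0.0072 to 0.71.

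Nano-sized ZnO raised heat shock, immediate early and metallothionein genes in RKO cells, list calls that were lost with an estimated correlation (adjusted p = 0.072, 0.45 and 0.45 with an estimated correlation). HSPA6, an inducible HSP70 chaperone, rose by 4.55 ± 0.12 (23.4-fold; 4.24 with BSA and 4.64 with TNF; chromosome 1, 158309213 to 158309272; adjusted p = 3.3e-15). HSPH1 rose by 4.13 ± 0.099, the stress-induced GADD45B by 4.14, the transcription factors FOS and EGR2 by 3.97 and 3.87, IER5 by 3.91, RGS2, a brake on G-protein signalling, by 3.86, and the co-chaperone DNAJB4 by 3.81. The zinc-binding MT1F rose by 3.77 and the zinc exporter SLC30A1 by 3.41. Falls were led by NFKBIA (-2.34 ± 0.44), whose 2 arms were unequal at -0.17 with BSA and -3.46 with TNF, the growth regulator MYC (-2.23 ± 0.14; chromosome 8, 128822450 to 128822509), ANGPTL4 (-2.12), RRS1, a ribosome assembly factor (-1.97), SNORA24 (-1.94), FEM1A (-1.94), the methyltransferase PRMT6 (-1.90) and TLR3, a sensor of double-stranded RNA (-1.85). Other probes gave as little as 0.30 for IER5 and 2.98 for GADD45B, and 0.07 for MYC.

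The comparison asked what each particle does whatever the pretreatment, and for nanoZnO in RKO it called 6770 of 13608 genes, 3500 higher and 3270 lower. At least 2-fold, 414 rose and 163 fell. All 24 heat shock genes rose, with BAG3 at 3.00, and all 24 did adjusted over the list alone (camera adjusted p = 1.1e-19, adjusted p = 0.072 with an estimated correlation). Of 28 immediate early genes 20 rose and 4 fell, as many adjusted over the list alone (camera adjusted p = 1.1e-06, adjusted p = 0.45 with an estimated correlation). Of 11 metallothionein and zinc export genes 7 rose and 0 fell, as many adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.45 with an estimated correlation). Other probes of this list, such as MT1B and MT1G, had log2 Cy5 signals of 17.4 and 17.5 in TNF-alone RKO arrays, near the line's highest value of 18.6, and paralogs can bind the same probe. Of 20 ATF4 targets, genes of the integrated stress response, 15 rose, such as ATF3 (3.50) and DDIT3 (2.06), and 1 fell, as many adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.45 with an estimated correlation). Of 23 NRF2 targets 11 rose, such as HMOX1, which breaks down heme (3.63), and GCLM, of glutathione synthesis (2.37), as many adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.45 with an estimated correlation).

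Hypoxia response genes in RKO rose for 15 of 24 and fell for 3 with nanoZnO, with ADM at 2.49, as many adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes rose for 14 of 23 and fell for 1, with HMGCS1 at 1.02, as many adjusted over the list alone (camera adjusted p = 0.0059, adjusted p = 0.45 with an estimated correlation). Cell cycle genes fell for 19 of 35, such as MKI67 (-1.18) and PLK1 (-0.90), and rose for 7, such as CDC6 (1.05); adjusted over the list alone 20 fell and 7 rose (camera adjusted p = 0.0087, adjusted p = 0.45 with an estimated correlation). The other 9 lists did not pass. Of 19 other zinc transporters 2 rose and 4 fell, with the importer SLC39A10 at -0.80 (camera adjusted p = 0.47). The RKO nanoZnO and TNF-alone arrays shared a slide, and the spread between the arms of a particle leaves out that between slides and cultures. In a comparison of each particle with the particles without zinc, with the spread taken between those particles, which changes both control and spread and is called the between-particle comparison, 2599 genes passed, 2536 of them among the 6770 and in the same direction.

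Micron-sized ZnO in RKO raised metallothionein and heat shock genes and 10 of 23 NRF2 targets, list calls that were lost with an estimated correlation (adjusted p = 0.17, 0.11 and 0.74 with an estimated correlation). MT1F rose by 3.86 ± 0.075 (14.5-fold; 3.69 with BSA and 3.86 with TNF; chromosome 16, 55250578 to 55250637; adjusted p = 7.5e-17), HSPA6 by 3.59, SLC30A1 by 2.85 (chromosome 1, 208137237 to 208137296), HMOX1 by 2.82, DNAJB4 by 2.66, RFPL2 by 2.63, ZFAND2A, a stress-induced protein of the proteasome, by 2.43, and the metallothionein pseudogene MT1JP by 2.39. Among falls were SLC39A10 (-1.75 ± 0.088), ANGPTL4 (-1.64), IL11 (-1.63), AHNAK (-1.58), SMNDC1 (-1.54), the nuclear import factor IPO7 (-1.45), KLF2 (-1.36) and SCG5 (-1.31). Other probes gave -0.12 for AHNAK, -0.16 for IPO7 and -0.09 for KLF2. IPO7 did not pass with the ratio against 0 (-0.58, adjusted p = 0.11; range 0.00057 to 0.11), nor IPO7, AHNAK and SCG5 in the between-particle comparison. The test called 5218 genes, 2637 higher and 2581 lower, of which 111 rose and 18 fell at least 2-fold.

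Heat shock genes in RKO rose for 22 of 24 with microZnO, as many adjusted over the list alone (camera adjusted p = 1.7e-17, adjusted p = 0.11 with an estimated correlation). Metallothionein and zinc export genes rose for 10 of 11, as many adjusted over the list alone (camera adjusted p = 1.8e-10, adjusted p = 0.17 with an estimated correlation). NRF2 targets rose for 10 of 23, such as GCLM (1.86), and for 11 adjusted over the list alone (camera adjusted p = 9.1e-05, adjusted p = 0.74 with an estimated correlation). Immediate early genes rose for 10 of 28, such as FOS (1.84), and fell for 2, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.83 with an estimated correlation). ATF4 targets rose for 10 of 20 and fell for 2, as many adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.83 with an estimated correlation). The microZnO arrays were on 1 slide scanned on another day, so microZnO and that slide cannot be told apart. In the between-particle comparison, 833 genes were called, 801 of them among the 5218 and in the same direction.

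In Caco-2, nano-sized ZnO raised metallothionein and heat shock genes, and also NRF2 targets and immediate early genes, whose calls were lost with an estimated correlation (adjusted p = 0.075 and 0.14 with an estimated correlation). DUSP1, a phosphatase that turns off MAP kinases, rose by 3.60 ± 0.18 (12.2-fold; chromosome 5, 172127902 to 172127961; adjusted p = 7.9e-11). The metallothioneins MT1E, MT1F, MT1B, MT1L and MT1G rose by 3.56, 3.48, 3.24, 2.99 and 2.94, although second probes gave 1.35 for MT1E and -0.21 for MT1L. HSPA6, well above background on 1 of 2 control arrays, rose by 3.12, HMOX1 by 3.01, AKR1B10, which detoxifies aldehydes, by 2.65, SLC7A11, a cystine importer, by 2.46, and the zinc transporter SLC30A2 by 2.45. Among falls were PRR15L (-1.96 ± 0.11), the nitric oxide synthase NOS2 (-1.72), VAV3 (-1.57), the transcription factors FOXA1 (-1.39) and NR2F2 (-1.30), L3MBTL3 (-1.31), the potassium channel KCNJ2 (-1.30) and TNFRSF11B, a decoy receptor (-1.26). A second VAV3 probe gave -0.14. VAV3 turned to 0.33 against nanoFe2O3 on the same slide (adjusted p = 0.17; range 3.2e-08 to 0.57). NOS2, VAV3, L3MBTL3 and KCNJ2 did not pass in the between-particle comparison. On that slide MT1F was 4.43, MT1E 4.66, HSPA6 3.30 and HMOX1 3.03 higher with nanoZnO than with nanoFe2O3. Several falls were smaller there, with PRR15L at -0.96, NOS2 at -0.84, NR2F2 at -0.81, L3MBTL3 at -0.75 and KCNJ2 at -0.31, while FOXA1 was at -2.34.

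The nanoZnO test in Caco-2 called 5253 of 16179 genes, 1996 higher and 3257 lower, with 155 rises and 26 falls of at least 2-fold. The balance turned in the between-particle comparison, with 292 higher and 241 lower. The main fit assumes that TNF and nanoZnO effects add. However, the TNF effect with nanoZnO differed from that with the other particles for 2528 genes. For those genes a common nanoZnO effect may not describe both arms. These calls rest on the only pair of nanoZnO arrays in the line. All 11 metallothionein and zinc export genes rose, with a median of 2.79, as many adjusted over the list alone (camera adjusted p = 1e-27, adjusted p = 0.0062 with an estimated correlation). Heat shock genes rose for 23 of 25, and for 24 adjusted over the list alone (camera adjusted p = 2.6e-31, adjusted p = 0.0062 with an estimated correlation). Immediate early genes rose for 23 of 28, and for 26 adjusted over the list alone (camera adjusted p = 1.1e-20, adjusted p = 0.14 with an estimated correlation). NRF2 targets rose for 19 of 25, and for 20 adjusted over the list alone (camera adjusted p = 5.3e-15, adjusted p = 0.075 with an estimated correlation). ATF4 targets rose for 14 of 23, such as ATF3 (2.48), and fell for 2, as many adjusted over the list alone (camera adjusted p = 6.4e-06, adjusted p = 0.33 with an estimated correlation). Hypoxia genes rose for 14 of 26, such as ADM (1.83), and fell for 4, as many adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.18 with an estimated correlation). The other 11 lists did not pass. The count was 3466 without TNF-alone replicate 2 and 533 in the between-particle comparison, 507 of these shared in the same direction.

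Micron-sized ZnO in Caco-2 raised metallothionein and heat shock genes and lowered more genes than it raised by at least 2-fold. MT1F rose by 3.87 ± 0.075 (14.6-fold, adjusted p = 8.5e-17), MT1E by 3.81, HSPA6 by 3.61 and the co-chaperone DNAJA4 by 3.57. MT1B rose by 3.54, HMOX1 by 3.27, MT1L by 3.26, MT1M by 3.20 and SLC30A2 by 2.91. The log2 Cy5 signal of MT1M was 10 with TNF alone and 16.6 with microZnO. That gap is wider than the change of its ratio, which also depends on the Cy3 control, and the cause was not tested. The HSPA6 rise rests on the same control arrays as with nanoZnO, not all of them well above background. DKK1, an inhibitor of Wnt signalling, fell by 4.03 ± 0.43 (-3.99 with BSA and -3.95 with TNF; chromosome 10, 53746693 to 53746752; adjusted p = 4.7e-07), TNFRSF11B by 3.72, FOXA1 by 3.35, ANKRD1 by 3.34, and ALB, which encodes albumin, by 3.25 ± 0.35 (chromosome 4, 74650377 to 74651050). APOH, a plasma apolipoprotein, fell by 3.23, the ubiquitin ligase RNF128 by 3.14 and the growth factor EREG by 3.12. Other probes gave -0.01 for ALB, -0.86 for EREG, -1.66 for RNF128, 0.14 for DNAJA4, 1.77 for MT1E and -0.04 for MT1L. The test called 7713 genes, 3143 higher and 4570 lower, with 127 rises and 443 falls of at least 2-fold.

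All 11 metallothionein and zinc export genes rose with microZnO in Caco-2, with a median of 3.17, as many adjusted over the list alone (camera adjusted p = 2.1e-19, adjusted p = 0.035 with an estimated correlation). Heat shock genes rose for 23 of 25, and for 24 adjusted over the list alone (camera adjusted p = 5.8e-20, adjusted p = 0.035 with an estimated correlation). ATF4 targets rose for 14 of 23, such as DDIT4 (1.65), and fell for 2, as many adjusted over the list alone (camera adjusted p = 0.00025, adjusted p = 0.78 with an estimated correlation). NRF2 targets rose for 12 of 25 and fell for 4, such as the exporter ABCC2 (-2.24), with 12 and 5 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.78 with an estimated correlation). NF-kB targets fell for 21 of 41, such as CXCL1 (-3.05) and CXCL2 (-2.66), and rose for 3, with 22 and 3 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.78 with an estimated correlation). In iron handling (camera adjusted p = 0.58), HEPH, a ferroxidase of the gut, fell by 2.02. In the same arrays 7 of 14 genes listed as non-epithelial cell markers fell and 2 rose (camera adjusted p = 0.44). The mean log2 Cy5 signal of enterocyte markers was 9.79 with BSA and 9.75 with TNF on these arrays and 10.41 to 11.3 on the other Caco-2 arrays, a difference that was not tested. As in RKO, particle and slide cannot be told apart. In the between-particle comparison 3814 genes were called, 3461 shared in the same direction.

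Particle size was compared at the same dose of ZnO, on different slides and scan days. In RKO, immediate early and heat shock genes were higher with nanoZnO, calls that were lost with an estimated correlation (adjusted p = 0.69 and 0.46 with an estimated correlation). RASD1, a small GTPase, rose by 3.58 with nanoZnO and was 0.06 with microZnO, a difference of 3.51 ± 0.30 (chromosome 17, 17338512 to 17338571; adjusted p = 3.1e-08). The differences of SLC6A13, HSPH1 and IER5 were 3.00, 2.94 and 2.91, and second probes gave 1.01 for RASD1, 1.33 for SLC6A13 and 0.82 for IER5. MYC (-1.97 ± 0.14), the matrix protease MMP1 (-1.64), PRMT6 (-1.56) and TLR3 (-1.49) were lower with nanoZnO, but another MYC probe gave 0.02. MMP1 did not pass in the between-particle comparison, where its log2 difference is the same and only the spread differs. The test called 6624 genes, 3426 higher and 3198 lower with nanoZnO. Heat shock genes were higher for 22 of 24 (23 adjusted over the list alone; camera adjusted p = 3.2e-10, adjusted p = 0.46 with an estimated correlation), immediate early genes for 20 of 28 with 3 lower (21 and 3 adjusted over the list alone; camera adjusted p = 6.4e-07, adjusted p = 0.69 with an estimated correlation). ATF4 targets were higher for 14 of 20 with 1 lower, as many adjusted over the list alone (camera adjusted p = 0.00018, adjusted p = 0.69 with an estimated correlation), and hypoxia genes for 16 of 24 with 3 lower, as many adjusted over the list alone (camera adjusted p = 0.0068, adjusted p = 0.69 with an estimated correlation). Cell cycle genes were lower for 20 of 35, such as AURKA (-1.0), and higher for 8, as many adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.46 with an estimated correlation). Metallothioneins were lower for 7 of 11 and higher for 1, as many adjusted over the list alone (camera adjusted p = 0.0064, adjusted p = 0.69 with an estimated correlation), a call that ended with the ratio against 0 (0.066) and in the between-particle comparison (0.14, range 0.0018 to 0.69 over all alternatives).

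In Caco-2, immediate early genes were higher with nanoZnO than with microZnO (adjusted p = 0.47 with an estimated correlation). ALB was 0.58 with nanoZnO and -3.25 with microZnO, a difference of 3.83 ± 0.34 (adjusted p = 8.5e-08), and the differences of APOH, DKK1 and CXCL8 were 3.55, 3.51 and 3.20. Another ALB probe gave 0. EFEMP1 (-1.99 ± 0.21), FAM78A (-1.94), the transketolase-like TKTL1 (-1.79) and the chemokine CXCL14 (-1.66) were lower. EFEMP1 did not pass in the between-particle comparison, where its log2 difference is the same and only the spread differs. The test called 6989 genes, 3591 higher and 3398 lower. Immediate early genes were higher for 26 of 28, such as EGR1 (2.67), and for 28 adjusted over the list alone (camera adjusted p = 8.4e-13, adjusted p = 0.47 with an estimated correlation). NRF2 targets were higher for 15 of 25 and lower for 3 (16 and 3 adjusted over the list alone; camera adjusted p = 0.00078, adjusted p = 0.56 with an estimated correlation), and NF-kB targets higher for 18 of 41 and lower for 3, as many adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.56 with an estimated correlation). Hypoxia genes were higher for 11 of 26 and lower for 3, as many adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.56 with an estimated correlation), and aryl hydrocarbon receptor targets higher for 6 of 12 and lower for 1, as many adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.47 with an estimated correlation; 0.05 with the stricter filter and 0.051 in the between-particle comparison, in a range of 0.017 to 0.47). Cell cycle genes were lower for 16 of 35 and higher for 3, as many adjusted over the list alone (camera adjusted p = 0.0054, adjusted p = 0.47 with an estimated correlation). Metallothioneins were lower for 7 of 11, and for 9 adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.56 with an estimated correlation; 0.068 with the ratio against 0 and 0.19 in the between-particle comparison, in a range of 0.004 to 0.56). The between-particle comparison left 713 calls in RKO, 435 higher and 278 lower with nanoZnO. In Caco-2 it left 729, 610 higher and 119 lower.

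Between the lines, most metallothionein probes changed more in Caco-2 with either form of ZnO, but most RKO probes began near the top of the range, and the list calls were lost with an estimated correlation (adjusted p = 0.40 for nanoZnO and 0.18 for microZnO with an estimated correlation). With nanoZnO, MT1B was 0.08 in RKO and 3.24 in Caco-2, a difference of -3.15 ± 0.15 (adjusted p = 7.5e-11), and MT1G, MT1E and MT1L differed by -2.91, -2.88 and -2.64. The phosphatase DUSP2 (3.44 ± 0.16), the transporter SLC6A13 (3.16), the Notch target HES1 (3.11) and ID2 (2.95) were higher in RKO. Other probes gave 0.10 for HES1, 1.26 for SLC6A13, -0.44 for MT1E and 0.85 for MT1L. The test called 5454 of 13500 genes, 3294 more positive in RKO and 2160 less. Metallothionein and zinc export genes were less positive in RKO for 9 of 11 and more for 2, as many adjusted over the list alone (camera adjusted p = 1.6e-09, adjusted p = 0.40 with an estimated correlation). Heat shock genes were more positive in RKO for 14 of 24 and less for 2, as many adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.98 with an estimated correlation). A high start may limit the rise that metallothionein probes can show in RKO, which was not tested. MT1B was 17.4 in TNF-alone RKO arrays and 13 in Caco-2. MT2A was saturated on 2 of 16 arrays in each line, but MT1B, MT1G, MT1E and MT1L on 0 of 16 in RKO. MT1F, which began at 9.8 in RKO and 12.1 in Caco-2, rose by 3.77 and 3.48 with nanoZnO and by 3.86 and 3.87 with microZnO. The log2 Cy5 signal of SLC30A1 was 12.2 with TNF alone and 15.5 with nanoZnO in RKO, and 12.5 and 14.2 in Caco-2.

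With microZnO, MMP1 rose by 1.96 in RKO and was -2.72 in Caco-2, a difference of 4.67 ± 0.38 (adjusted p = 7.5e-08), and CNKSR3, CXCL3 and CXCL2 differed by 3.54, 3.54 and 3.43. Second probes gave 1.57, 0.26 and 1.91. FAM78A (-2.95) and SLC30A2 (-2.81 ± 0.19, with 0.09 in RKO and 2.91 in Caco-2) changed more in Caco-2. The differences of MT1B (-2.88) and MT2A (-2.71) may be limited by the top of the range, which was not tested. With microZnO the log2 Cy5 signal was 17.6 in RKO and 17.2 in Caco-2 for MT1B, and 18.1 and 18.3 for MT2A. MT1B was saturated on 0 of 16 RKO arrays. The test called 4483 genes, 2804 more positive in RKO and 1679 less. Metallothionein and zinc export genes were less positive in RKO for 9 of 11 and more for 1, as many adjusted over the list alone (camera adjusted p = 7.8e-13, adjusted p = 0.18 with an estimated correlation), and heat shock genes less for 7 of 24 and more for 1, as many adjusted over the list alone (camera adjusted p = 0.00061, adjusted p = 0.70 with an estimated correlation). In the between-particle comparison 586 genes were called for nanoZnO and 1069 for microZnO.

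**Figure D2:**
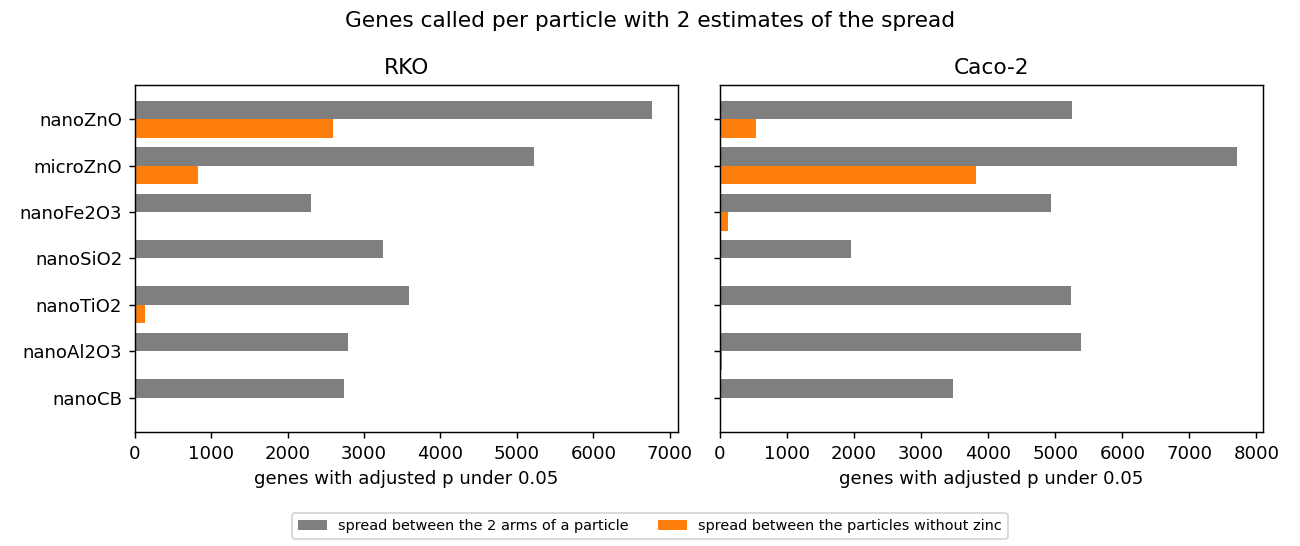
Bars give the number of genes with an adjusted p under 0.05 per particle, in RKO and Caco-2, with the spread taken between the 2 arms of a particle and TNF alone as control, or between particles with the particles without zinc as control. In RKO, nanoZnO has 6770 and 2599 calls and nanoFe2O3 2302 and 0; in Caco-2, microZnO has 7713 and 3814 and nanoCB 3479 and 2.

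The particles without zinc moved fewer genes by at least 2-fold in RKO, and most of their calls were lost in the between-particle comparison. NanoFe2O3 raised AOX1 (1.38 ± 0.074), MMP1 (1.34) and the stromelysin MMP3 (1.16) and lowered EGR2 (-1.0), the Notch target HEY1 (-0.94) and DNAJB4 (-0.94), with 1185 genes higher and 1117 lower. NanoSiO2 raised the trypsin inhibitor SPINK1 (2.23 ± 0.36), LAIR2 (1.66) and MMP3 (1.66) and lowered SLC30A1 (-1.56) and the noncoding RNA NEAT1 (-1.26), with 1877 higher and 1377 lower. SPINK1 was well above background on 1 of 2 control arrays. NanoTiO2 lowered the chaperone subunit PFDN4 (-2.47 ± 0.087; chromosome 20, 52265292 to 52265351), the histone gene H4C3 (-2.14) and the elongation factor EEF1B2 (-2.11), and raised EGR3 (0.86), FAM13B (0.84) and USP36 (0.74), with 1669 higher and 1916 lower. NanoAl2O3 raised LAIR2 (1.30), the interferon-induced IFIT1 (0.97) and NT5E (0.96) and lowered H4C3 (-1.42), H4C13 (-1.21) and NEAT1 (-1.09), with 1634 higher and 1152 lower. NanoCB raised CALB2 (1.35), TAGLN, an actin-binding protein (1.04), and OPCML (1.01) and lowered NEAT1 (-1.29), SERPINB9 (-0.98) and HMOX1 (-0.97), with 1439 higher and 1299 lower. At least 2-fold, the changed genes numbered 5, 11, 61, 8 and 5 in this order. Against 0, HEY1 was -0.22, FAM13B 0.39, USP36 0.21, OPCML 0.26 and HMOX1 -0.27, and none of these passed.

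The total RKO counts were 2302, 3254, 3585, 2786 and 2738 of 13608 genes, and single arrays moved them. Without the TNF arm they were 493 (nanoFe2O3), 1899 (nanoSiO2), 1717 (nanoTiO2), 1464 (nanoAl2O3) and 911 (nanoCB), and without the BSA arm 1467 for nanoSiO2 and 1464 for nanoAl2O3. Without TNF-alone replicate 1 they were 782 (nanoFe2O3), 1289 (nanoSiO2), 1726 (nanoAl2O3) and 1379 (nanoCB), and without replicate 2 nanoAl2O3 gave 1679. EGR3 with nanoTiO2 did not pass without any 1 of its 4 arrays (0.73 to 0.99). In the between-particle comparison, the limma counts were 0, 2, 131, 0 and 0, with 623, 410, 1853, 726 and 86 genes at an unadjusted p under 0.05. Chance alone at that threshold would give more genes than were counted for nanoFe2O3, nanoSiO2 and nanoCB. Of the 131 calls with nanoTiO2, 5 were higher and 126 lower.

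Metallothionein and zinc export genes were lower than with TNF alone for several of these particles in RKO: 10 of 11 fell with nanoSiO2, such as MT1E (-0.96), and adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 9.6e-10, adjusted p = 0.38 with an estimated correlation). With nanoAl2O3 8 fell, and 9 adjusted over the list alone (camera adjusted p = 3.1e-06, adjusted p = 0.46 with an estimated correlation), with nanoCB 8 fell and 1 rose, as many adjusted over the list alone (camera adjusted p = 3.7e-05, adjusted p = 0.80 with an estimated correlation). With nanoFe2O3 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.67 with an estimated correlation). The TNF-alone arrays used as control had mean log2 ratios of 0.745 and 0.647 for the list. With the ratio against 0 none of the 4 passed, and nanoCB and nanoFe2O3 changed direction. The adjusted p against 0 was 0.099 for nanoSiO2 (range 1.3e-11 to 0.38 over its alternatives), 0.95 for nanoAl2O3 (2.5e-07 to 0.95), 0.75 for nanoCB (6.1e-06 to 0.80) and 0.13 for nanoFe2O3 (0.0062 to 0.67). The list was still lower with nanoSiO2 in the between-particle comparison (camera adjusted p = 9e-06), which leaves out the TNF-alone arrays. There the calls for nanoAl2O3 and nanoCB were lost, and that for nanoFe2O3 changed direction and did not pass (0.25).

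ATF4 targets fell for 12 of 20 with nanoTiO2, such as DDIT4 (-1.64), and rose for 3, as many adjusted over the list alone (camera adjusted p = 3.5e-05, adjusted p = 0.99 with an estimated correlation). With nanoAl2O3 8 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.52 with an estimated correlation), with nanoCB 10 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.80 with an estimated correlation). With nanoFe2O3 7 fell and 1 rose, as many adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.67 with an estimated correlation). ASNS, which makes asparagine, was at -0.81 with nanoAl2O3, where another probe gave 0.20, -1.48 with nanoCB and -1.03 with nanoFe2O3. All 4 ATF4 calls changed direction with the ratio against 0, and in the between-particle comparison that of nanoFe2O3 changed direction and those of nanoAl2O3 and nanoCB were lost. Cell cycle genes rose for 19 of 35 with nanoTiO2 and 1 fell (20 and 2 adjusted over the list alone; camera adjusted p = 3.5e-05, adjusted p = 0.24 with an estimated correlation), for 17 with nanoAl2O3 and 1 fell (18 and 3 adjusted over the list alone; camera adjusted p = 1.8e-06, adjusted p = 0.12 with an estimated correlation), and for 12 with nanoCB (14 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.27 with an estimated correlation), and none of these 3 passed against 0, nor nanoTiO2 and nanoCB in the between-particle comparison. Interferon response genes rose for 8 of 29 with nanoAl2O3, such as PSMB8 (0.59), as many adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.52 with an estimated correlation). Lysosome and autophagy genes fell for 4 of 27 with nanoFe2O3, such as CTSK (-0.49), and for 5 adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.67 with an estimated correlation), a call that ended against 0.

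Cholesterol synthesis genes fell for 9 of 23 with nanoFe2O3 in RKO, such as the sterol carrier STARD4 (-0.87), and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 0.00069, adjusted p = 0.67 with an estimated correlation). With nanoAl2O3 10 fell, such as INSIG1 (-0.60), and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 5.8e-05, adjusted p = 0.46 with an estimated correlation). With nanoCB 8 fell, such as SQLE (-0.47), and 1 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.009, adjusted p = 0.87 with an estimated correlation). With nanoSiO2 6 rose, such as DHCR7 (0.35), as many adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.90 with an estimated correlation). The calls for nanoFe2O3, nanoAl2O3 and nanoCB ended with the ratio against 0, and that for nanoCB also in the between-particle comparison. Heat shock genes fell for 9 of 24 with nanoFe2O3, such as DNAJA1 (-0.56), and 11 adjusted over the list alone (camera adjusted p = 0.00054, adjusted p = 0.67 with an estimated correlation). With nanoSiO2 6 fell, such as DNAJB4 (-0.67), as many adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.90 with an estimated correlation). Immediate early genes fell for 3 of 28 with nanoFe2O3 and for 1 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.67 with an estimated correlation), a call that also ended against 0.

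In Caco-2, ALB was among the 3 largest rises with 4 of the 5 particles without zinc. Its other probes gave as little as 0.25 (nanoSiO2), 0.24 (nanoTiO2), 0.37 (nanoAl2O3) and 0.09 (nanoCB). The mean log2 Cy5 signal of enterocyte markers was 10.97 to 11.3 on the arrays of these 4 particles. It was 10.61 and 10.66 with TNF alone, and 10.59 and 10.61 with nanoFe2O3, a difference that was not tested. NanoFe2O3 raised the growth factor receptor PDGFRA (2.73 ± 0.27), the peptide UTS2 (2.64) and DKK1 (2.40) and lowered VAV3 (-1.89 ± 0.19), EFEMP1 (-1.88) and the hormone CRH (-1.71), with second probes at 0.95 for PDGFRA and -0.59 for VAV3, and with 2024 genes higher and 2917 lower. NanoSiO2 raised ALB (1.88 ± 0.35), the apolipoprotein APOA4 (1.52) and SPRR2G (1.47) and lowered LRP1B (-1.10), MTUS2 (-1.02) and ACP3 (-0.94), with 796 higher and 1155 lower. NanoTiO2 raised ALB (2.45), the plasma protein AHSG (2.06) and APOH (2.05) and lowered TMSB15A (-2.08), NUDT10 (-1.81) and PFDN4 (-1.63 ± 0.087), with 2423 higher and 2810 lower. NanoAl2O3 raised UTS2 (3.33 ± 0.31), ALB (2.48) and MYBPH (2.07) and lowered BPNT1 (-1.32), CXCL1 (-1.22) and TMEFF2 (-1.22), with 2874 higher and 2512 lower; the array design places the TMEFF2 probe in the mitochondrial genome, so its target is in doubt. NanoCB raised ALB (1.89), APOA4 (1.56) and PPBP (1.43), with a second APOA4 probe at 0.48, and lowered CYP1A1 (-2.13 ± 0.12; chromosome 15, 72799615 to 72799674) and CYP1B1 (-1.55 ± 0.16; chromosome 2, 38207095 to 38207154), enzymes that oxidise polycyclic aromatic compounds, and MTUS2 (-1.41), with 1467 higher and 2012 lower. At least 2-fold, 98, 18, 137, 74 and 36 genes changed in this order.

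The total Caco-2 counts were 4941, 1951, 5233, 5386 and 3479 of 16179 genes. Without the TNF arm they were 449 (nanoSiO2), 2543 (nanoTiO2), 3171 (nanoAl2O3) and 1200 (nanoCB), and without the BSA arm 1059 for nanoSiO2. Without TNF-alone replicate 2 they were 3072 (nanoFe2O3), 571 (nanoSiO2), 2927 (nanoAl2O3) and 1499 (nanoCB), and without replicate 1 nanoSiO2 gave 1283. ALB (1.63) and MTUS2 (-0.77) did not pass for nanoSiO2 without its TNF arm. In the between-particle comparison, the limma counts were 121, 0, 2, 39 and 2, with 1374, 263, 1011, 2062 and 545 genes at an unadjusted p under 0.05. There, chance alone at that threshold would give more genes than were counted for nanoSiO2 and nanoCB. Of the 60 genes the naming rule picked for particles without zinc in both lines, 51 did not pass there, 3 changed direction, and 6 kept their call: PFDN4 (-2.28) and EEF1B2 (-2.14) in RKO with nanoTiO2, VAV3 (-1.16) with nanoFe2O3, BPNT1 (-1.27) with nanoAl2O3, and CYP1A1 (-2.21) and CYP1B1 (-1.27) with nanoCB. The VAV3 call cannot be told apart from an effect of its slide. NanoFe2O3 shared that slide with nanoZnO alone, and VAV3 fell with nanoZnO too. VAV3 differed between these particles on the slide by 0.33 (limma adjusted p = 0.17).

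Immediate early genes rose for 16 of 28 with nanoCB in Caco-2, such as FOSB (1.15), and for 19 adjusted over the list alone (camera adjusted p = 2.4e-11, adjusted p = 0.61 with an estimated correlation), and for 14 with nanoTiO2, such as CCN2 (1.72), and 16 adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.46 with an estimated correlation). NF-kB targets rose for 14 of 41 with nanoTiO2 and fell for 4, as many adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.46 with an estimated correlation), and for 11 with nanoCB with 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.61 with an estimated correlation). Hypoxia genes rose for 15 of 26 with nanoTiO2 and fell for 1, as many adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.39 with an estimated correlation). Metallothionein and zinc export genes fell for 10 of 11 with nanoFe2O3, such as MT1M (-1.30), as many adjusted over the list alone (camera adjusted p = 9.4e-10, adjusted p = 0.19 with an estimated correlation), and for 10 with nanoTiO2, as many adjusted over the list alone (camera adjusted p = 7.5e-06, adjusted p = 0.42 with an estimated correlation). Heat shock genes fell for 12 of 25 with nanoFe2O3, and for 13 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.88 with an estimated correlation), and for 11 with nanoTiO2, as many adjusted over the list alone (camera adjusted p = 0.00089, adjusted p = 0.46 with an estimated correlation). Neither passed in the between-particle comparison. Aryl hydrocarbon receptor targets rose for 6 of 12 with nanoFe2O3, as many adjusted over the list alone (camera adjusted p = 0.009, adjusted p = 0.19 with an estimated correlation). With nanoTiO2 6 rose, such as UGT1A6 (0.57), and 7 adjusted over the list alone (camera adjusted p = 0.0085, adjusted p = 0.39 with an estimated correlation), and with nanoCB 4 fell (camera adjusted p = 0.089). Non-epithelial cell markers rose for 7 of 14 with nanoTiO2 and 1 fell (camera adjusted p = 0.052).

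NanoSiO2 in Caco-2 moved 5 lists by small amounts. Immediate early genes rose for 3 of 28, such as KLF10 (0.63), and for 6 adjusted over the list alone (camera adjusted p = 2.8e-06), and NF-kB targets rose for 3 of 41, such as NFKBIE (0.74), and fell for 2, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0046). Cell cycle genes fell for 11 of 35, such as KIF20A (-0.51), and 1 rose (13 and 2 adjusted over the list alone, camera adjusted p = 0.018). Cholesterol synthesis genes fell for 4 of 23, such as HSD17B7 (-0.47), and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0046). Endoplasmic reticulum chaperones fell for 3 of 18, such as HSP90B1 (-0.34), and for 4 adjusted over the list alone (camera adjusted p = 0.03). All 5 had adjusted p = 0.91 with an estimated correlation. The immediate early, NF-kB and cell cycle calls ended in the between-particle comparison, and that of the chaperones against 0. With nanoAl2O3 none of the 17 lists passed camera against TNF alone, with adjusted p = 0.086 for NF-kB targets and 0.091 for iron handling. In the between-particle comparison 3 lists were lower with nanoAl2O3: immediate early genes (camera adjusted p = 4.7e-13), NF-kB targets (2.9e-10) and ATF4 targets (0.031). No estimated correlation was computed in that setting.

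The test of TNF by particle asked whether TNF acts differently beside a particle than beside the others. In Caco-2 the TNF effect with nanoZnO stood apart: DKK1 was -2.45 between TNF and BSA arrays with nanoZnO and 0.19 on average with the others, a difference of -2.64 ± 0.14 (adjusted p = 1.8e-08), and EID3 (-2.21), ARL14 (-2.17), ARMCX2 (1.59) and TMSB15A (1.55) differed too. PBX2 differed for nanoAl2O3 (1.52). EID3 was lost with Agilent's processed ratios (-0.27) and turned to 0.18 with the deposited table (adjusted p = 1; range 1e-06 to 1). Of 2667 combinations called, 2528 were for nanoZnO, 877 higher and 1651 lower, and the 2 nanoZnO arrays are the only pair behind them. Without either array the nanoZnO term cannot be estimated, and 29 combinations of the other particles passed. The others were 28 for microZnO, 39 for nanoFe2O3, 6 for nanoSiO2, 14 for nanoTiO2, 42 for nanoAl2O3 and 10 for nanoCB. P-values were adjusted over all particles of a line together, so the many nanoZnO calls loosened the cutoff for the other particles. Without both Caco-2 nanoZnO arrays 12 of the 42 passed, PBX2 among them, and at most 4 for each of the others. Log2 differences moved little there, as for SNTB1 with microZnO (0.81 to 0.76, limma adjusted p = 0.048 to 0.52). That of MROH5 with nanoFe2O3 went from -0.61 to -0.58 (limma adjusted p = 0.049 to 0.54). Most calls for the other particles were thus lost once nanoZnO left the adjustment, though leaving out arrays also changes the spread. In RKO 6 combinations passed: for nanoZnO, NFKBIA (TNF effect 1.36 against 3.97, difference -2.61 ± 0.19, adjusted p = 8.1e-06), EFNA1 (2.08) and PCED1B (-1.07), for microZnO, KIF25-AS1 (1.39) and HOXB8 (1.27), and for nanoFe2O3, OR10J5 (-0.88). In a separate fit for RKO 1 combination passed. Leaving out 1 array gave 3 combinations for either nanoSiO2 array and 2 for either array of nanoTiO2, nanoAl2O3 or nanoCB. Without 1 nanoZnO array 1 passed and without 1 microZnO array 2, where the term of that particle itself cannot be estimated. For nanoSiO2, nanoTiO2, nanoAl2O3 and nanoCB the limma count was 0, with 362, 269, 290 and 542 genes at an unadjusted p under 0.05. Chance alone at that threshold would give more genes than each of these counts. The same holds for the RKO particles with calls: 426 for nanoZnO, 407 for microZnO and 585 for nanoFe2O3. In Caco-2 it holds for microZnO (678), nanoSiO2 (403), nanoTiO2 (445), nanoAl2O3 (487) and nanoCB (396). It does not hold there for nanoFe2O3 (1224) or nanoZnO (5990).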

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

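The test of a weaker zinc exposure and the 3 tests on the falls with microZnO were chosen only after the result was seen. Of the 32 genes named for TNF, 3 had 1 pair far from the other 6, where chance gives about 1 in 20. NFKBIA rose by 1.36 in the RKO nanoZnO pair and by 3.76 to 4.18 in the others. ANGPTL4 was -1.22 in the RKO microZnO pair and -0.46 to -0.23 in the others, and SPTSSB was -2.04 in the Caco-2 nanoZnO pair and -0.87 to -0.40 in the others.

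The TNF effect differed between the lines for 2152 genes. The differences, RKO minus Caco-2, were 2.60 for TRAF1, 2.32 for BIRC3, 2.27 for ICAM1, 2.06 for NFKBIA, -2.22 for COXFA4L3, -1.93 for PLAT, -1.92 for UBD and -1.82 for CXCL10. Exchanging TNF and BSA within pairs gave as many genes in 1 of 64 arrangements in each line, the real one. No lower share is possible with 64 arrangements, so chance is argued against in both lines but not excluded. The real counts were 2529 in RKO and 4821 in Caco-2, and the highest others were 448, with the nanoFe2O3 pair exchanged, and 3352, with the nanoZnO pair exchanged. For the line difference, 1 of 100 splits of the 14 pair differences, the real one, gave as many genes (2096 on pair differences alone, highest other 35). Again no lower share was possible with 100 splits, so chance is argued against but not excluded.

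The nanoZnO effect differed between the lines for 5454 genes, by 3.44 for DUSP2, 3.16 for SLC6A13, 3.11 for HES1, 2.95 for ID2, -3.15 for MT1B, -2.91 for MT1G, -2.88 for MT1E and -2.64 for MT1L. The microZnO effect differed for 4483 genes, by 4.67 for MMP1, 3.54 for CNKSR3, 3.54 for CXCL3, 3.43 for CXCL2, -2.95 for FAM78A, -2.88 for MT1B, -2.81 for SLC30A2 and -2.71 for MT2A. In RKO these metallothionein probes were near the top of the range without zinc. In RKO the TNF effect differed by particle for 6 combinations: EFNA1 (2.08), NFKBIA (-2.61) and PCED1B (-1.07) with nanoZnO, KIF25-AS1 (1.39) and HOXB8 (1.27) with microZnO, and OR10J5 (-0.88) with nanoFe2O3. Leaving out either nanoSiO2 array gave 3 combinations and either array of nanoTiO2, nanoAl2O3 or nanoCB 2. Without 1 nanoZnO array 1 passed and without 1 microZnO array 2, where the term of that particle itself cannot be estimated.

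In Caco-2 the TNF effect differed by particle for 2667 combinations, 2528 of them with nanoZnO, whose term rests on 1 pair. Without either nanoZnO array that term cannot be estimated, and 29 combinations of the other particles passed. ARMCX2 (1.59), TMSB15A (1.55), DKK1 (-2.64), EID3 (-2.21) and ARL14 (-2.17) were among those with nanoZnO, and PBX2 (1.52) with nanoAl2O3. A weaker zinc exposure in the TNF arm as the whole cause would need most of these genes to show a smaller change of the same sign there, and 43.6% did. It stays open as part of the cause: the mean log2 ratio was lower with TNF than with BSA for metallothioneins (2.755 and 3.091), heat shock genes (1.21 and 1.503) and NRF2 targets (0.773 and 1.28). With Agilent's processed ratios 69.1% of the 2528 calls kept call and direction, and these ratios gave 2383 calls for nanoZnO themselves. This argues against the choice between the 2 ways of background correction and normalization as the whole cause. Both ways apply loess or LOWESS to the same scans, so an effect that they share could not be seen. Drift of the culture state may account for part of it. Across genes, not independent replicates, the arm difference had an absolute correlation of 0.44 with the main axis of the Caco-2 arrays without zinc. The highest for another particle was 0.29. The mean log2 Cy5 signal of enterocyte markers was 10.41 with TNF and 11.02 with BSA. This gap was the widest of the Caco-2 pairs and was not tested. A response to TNF that depends on zinc stays open and untested, since each arm is 1 array.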

How the results depend on the processing

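Some alternatives were chosen only after seeing the data: all transcripts, and each particle against the particles without zinc, called each particle against the others. Leaving out the Caco-2 nanoZnO or the microZnO arrays, and nanoZnO against nanoFe2O3 within their slide, were also chosen then. Slide as a random block was not run, since the slides lie within the model's terms and their correlation could not be estimated. Signal over background limits the dim genes: Cy5 spots well above background ranged from 58% to 86.6% across arrays. Where no reason is given, the cause was not tested.

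With the ratio against 0, the counts were 3973 for TNF in RKO, 3679 for nanoFe2O3 in RKO, 1128 for nanoCB in RKO and 1272 for TNF by particle in Caco-2. The direction turned for ATF4 targets in RKO with nanoFe2O3 (adjusted p = 0.00083, range 0.00083 to 0.67 over its alternatives), nanoTiO2 (0.28, range 1.6e-05 to 0.99), nanoAl2O3 (0.14, range 1.6e-05 to 0.52) and nanoCB (0.015, range 7.3e-06 to 0.80), and for metallothioneins in RKO with nanoFe2O3 (0.13, range 0.0062 to 0.67) and nanoCB (0.75, range 6.1e-06 to 0.80). This alternative drops the TNF-alone arrays as the only control. TNF-alone arrays against 0 gave 6935 genes in RKO and 7867 in Caco-2. TNF by particle in RKO gave 14 combinations with Agilent's ratios, 15 with the deposited table, 3 with the stricter filter, 1 in a separate fit, 19 without the Caco-2 nanoZnO arrays and 2 without the microZnO arrays. EID3 turned to 0.18 with the deposited table. A separate fit gave 3552 for nanoFe2O3 in RKO, 847 for nanoSiO2 in Caco-2 and 2236 for nanoCB in Caco-2. Without the Caco-2 nanoZnO arrays the counts were 3642 for nanoFe2O3 in RKO, 3357 for nanoSiO2 in Caco-2 and 29 for TNF by particle in Caco-2. Both lines share 1 model, so leaving out Caco-2 arrays moved the RKO counts only through the shared spread and its degrees of freedom. Within the slide VAV3 turned to 0.33.

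With each particle against the others, which cancels what all particles share and has fewer degrees of freedom, limma called 2599, 833, 0, 2, 131, 0 and 0 genes in RKO for nanoZnO, microZnO, nanoFe2O3, nanoSiO2, nanoTiO2, nanoAl2O3 and nanoCB. In Caco-2 it called 533, 3814, 121, 0, 2, 39 and 2. Counts at an unadjusted p under 0.05 were 623, 726 and 86 where RKO had 0, and 263 where Caco-2 had 0. Chance alone at that threshold would give more genes than the counts of 623, 86 and 263. Nano against micro gave 713 in RKO and 729 in Caco-2, and the line differences 586 for nanoZnO and 1069 for microZnO. ALB turned to -0.02 for nanoSiO2 and 0 for nanoCB, MTUS2 to 0.03 for nanoSiO2, and in RKO with nanoFe2O3 ATF4 targets (adjusted p = 0.26, range 0.00083 to 0.67) and metallothioneins (0.25, range 0.0062 to 0.67) turned too.

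Leaving out each array in turn gave 1905 to 2488 genes for TNF in RKO, 4001 to 5598 for TNF in Caco-2 and 1765 to 2976 for their difference. In RKO the ranges were 5214 to 6014 for nanoZnO, 3637 to 4219 for microZnO, 493 to 1977 for nanoFe2O3, 1289 to 2451 for nanoSiO2, 1717 to 2666 for nanoTiO2, 1464 to 1726 for nanoAl2O3 and 911 to 2135 for nanoCB. In Caco-2 they were 3466 to 6780, 6173 to 6670, 3072 to 3803, 449 to 1283, 2543 to 4213, 2927 to 4324 and 1200 to 2608 in this order. Nano against micro ranged from 5126 to 5336 in RKO and 5115 to 8118 in Caco-2, the line differences from 4269 to 6358 for nanoZnO and 3480 to 3927 for microZnO, and TNF by particle from 1 to 5 in RKO and 29 to 2759 in Caco-2, where a particle whose array is left out has no such term.

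Named genes that kept direction and call numbered 200 with the ratio against 0 (8 lost), 206 without background subtraction (2 lost), 204 with Agilent's ratios (4 lost), 204 with the deposited table (3 lost), 203 with the stricter filter (1 lost), 179 in separate fits (5 lost), 93 with each particle against the others (60 lost) and 208 with no filter or all transcripts (0 lost). Of 91 called list results, 70 kept theirs with the ratio against 0 and 7 with an estimated correlation. With each particle against the others, which has no lists for TNF, 60 kept theirs, 15 lost it and 2 turned.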

Other observations

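Of the tests below, those on the falls with microZnO, those of single genes and the comparison of each particle with the others were chosen only after the result was seen. In Caco-2, the TNF effect beside nanoAl2O3, which rests on 1 pair of arrays, was higher than beside the other particles for the interferon-induced IFIT1 (1.14 ± 0.17, adjusted p = 0.00065) and USP18 (0.57, adjusted p = 0.0037). Without the nanoZnO arrays they were 1.08 (adjusted p = 0.011) and 0.60 (adjusted p = 0.048), while DDX60 (0.68) and MX2 (0.58) no longer passed. Beside nanoAl2O3, 487 of 16165 genes had an unadjusted p under 0.05 in limma, fewer than chance alone would give. Set against the other particles without zinc of the line, 5 of the 17 lists passed for nanoCB in Caco-2. Aryl hydrocarbon receptor targets (camera adjusted p = 2.3e-10) and endoplasmic reticulum chaperones (0.00025) were lower. Immediate early genes (5.2e-11), metallothioneins (1e-07) and NF-kB targets (5e-05) were higher. Against TNF alone the receptor targets (0.089), the chaperones (0.051) and metallothioneins (0.089) did not pass, and no estimated correlation was computed in this setting.

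With microZnO in Caco-2, 443 genes fell at least 2-fold. Enterocyte markers had a lower mean log2 Cy5 signal on these arrays (9.75 and 9.79) than on the other Caco-2 arrays (10.41 to 11.3). An effect of slide and scan day on the probes is argued against by a median change of -0.05 for the 302 of these genes measured in RKO on the same slide. Another reference RNA is argued against by a median Cy3 difference of -0.04 over the 443 genes. Drift of the culture state stays open. The median SD of these genes over the Caco-2 conditions without zinc was 0.306, and 0.118 for the other genes, a ratio of 2.6. That ratio cannot decide on drift, because these conditions include the TNF-alone arrays against which the genes were picked. The conditions also differ in particle and slide. A response of Caco-2 to micron-sized ZnO stays open and untested against that drift, since all microZnO arrays share 1 slide.

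Of 35655 calls over the 10 comparisons of particles without zinc, 263 were left, or 0.74%, when each particle was set against the others with the spread taken between them. Spread between slides and cultures may account for much of this loss, but that setting also changes the control, cancels a response shared by all particles and has fewer degrees of freedom, so the loss is not put down to the spread alone. Responses to single particles without zinc stay open.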
